A study of Mus musculus with 8 samples.

How the data were processed

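Hearts were collected from 8-week-old male mice of 3 genotypes, and total RNA was extracted with TRIzol and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. The conditional knockout group (cKO, n = 4) carried floxed Elmsan1 alleles together with a Cre recombinase transgene driven by the αMHC (Myh6) promoter, which is active in cardiomyocytes. The floxed group (n = 2) carried the floxed alleles without Cre, and the Cre group (n = 2) carried the transgene without floxed alleles. Each library was assigned to its group by its genotype label, and each column of the table to its library by the library name in the labels.

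The authors deposited 1 table of estimated counts per gene for 45706 Ensembl gene identifiers, and none of its columns was left out. Between 71.95% and 76.34% of the values above 0 in a library were whole numbers within a tolerance of 1e-06, and the rest had decimals, from which the values were read to be expected counts. The submitters' processing notes name STAR 2.5.1b, DESeq2 and the mouse builds mm10 and GRCm38. The program that estimated the counts, the annotation, the strand setting and the role of DESeq2 are not given in the sources used here. The estimated counts were rounded to whole numbers before testing, since the test needs counts and its design had been written for counts as deposited. Totals ranged from 17509564 to 25833259 estimated counts per library. With no strand setting given, reads from overlapping or antisense genes, and from near-identical copies, could have been split between them, so values of such genes are uncertain.

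Gene symbols, gene positions (GRCm38) and transcript lengths were taken from GENCODE M21. Of the 45706 identifiers 563 had no symbol there, 73 of them among the genes tested. Genes were filtered with filterByExpr, which left 15289 genes, and 21474 genes had 0 counts in every library. Library sizes were scaled by the trimmed mean of M values (TMM). The 8 libraries were fitted together with 3 group means and 5 residual degrees of freedom, using edgeR 4.0.16 in R 4.3.3 with robust dispersion. Contrasts were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at an adjusted p of 0.05. The main contrast set cKO against the mean of the floxed and Cre groups, each control group with the same weight. The others set cKO against floxed, cKO against Cre, and Cre against floxed. The last is also the test of the difference between the 2 comparisons before it. Standard errors of log2 fold changes (SE) were derived from the test statistic. Levels are given as CPM (library-scaled counts) with TMM factors, as mean ± SD. Totals, mitochondrial shares and the protocadherin cluster were compared between cKO and controls by exact two-sided permutation tests.

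A total of 44 gene lists covering cardiac muscle, metabolism, stress, cell types and the deacetylase complexes were fixed before the data were examined. Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) with an inter-gene correlation of 0.01, adjusted over the 44 lists, with camera at an estimated correlation and fry beside it. The genes named were also set by a rule fixed before the data were examined. It takes Elmsan1, 20 preset genes, and the 10 largest rises and 10 largest falls of the main contrast. For the latter the adjusted p had to be under 0.05, the mean at least 1 CPM, and all cKO values on 1 side of all control values. It adds up to 4 called members with the smallest p from each list that was called or had 2 called members, and the 4 largest rises and falls of each other contrast under the same filters. Gene models without a symbol or with only a predicted-gene name were counted and not named. A few genes outside the rule are said to be so where they appear.

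The alternatives fixed beforehand were other scalings (median-ratio, upper-quartile, library size alone), DESeq2 1.42.0, limma voom, no filter, a filter at a mean of 1 CPM, no robust fit, a replicate block, pooled controls, fits of only the groups compared, a minimum absolute log2 fold change of 1, lists without genes that more than 1 list holds, and leaving out each library. Alternatives chosen after seeing the data were a per-library offset for transcript length and GC content, and leaving out both floxed or both Cre libraries. Upper-quartile scaling was fixed beforehand for single genes and gene counts only, and its use for the gene lists was also chosen afterwards. In the replicate block, numbers 3 and 4 occur only in cKO, so those hearts add nothing to its comparisons between groups. The offset was a smooth function of the log2 length and the GC content of the longest transcript (mgcv 1.9.3), with values for 15216 of the 15289 tested genes (99.5%). Figures were drawn with matplotlib 3.10.9.

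The procedures were tested on simulated counts drawn from the libraries' means and dispersions. With 14933 genes and the main contrast, 82.3% of 96 genes changed 3-fold and 50.5% of 99 genes changed 1.5-fold were called, with 17 false calls. The same shares were 68.4% and 22.3% for cKO against floxed (14963 genes), with 10 false calls. They were 77.3% and 14.1% for cKO against Cre (14978 genes), with 16 false calls. For Cre against floxed they were 66.3% and 14.6% (15001 genes), with 10 false calls. In each of these simulations, false calls made up a larger share of all calls than the adjusted p threshold allows on average. The simulations therefore do not show that the threshold held. With a length trend added to the main contrast there were 2178 false calls without the offset (15052 genes) and 10 with it (14982 genes). That trend was linear in the log2 length that the offset uses, equal in every cKO library and without a GC term. The offset therefore removes it by construction, and the result does not show that it removes the trend in the real libraries. No 2 libraries of a group were copies, since chi-square per degree of freedom between them was 13.9 to 52.5.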

Results

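RNA sequencing measured transcript levels in 8 hearts of 8-week-old male mice, 4 with cardiomyocyte deletion of Elmsan1 (cKO), 2 floxed controls and 2 Cre controls. Elmsan1, also called Mideas, is a subunit of the MiDAC histone deacetylase complex, which holds Hdac1 or Hdac2 and Dnttip1. The comparisons address which transcripts differ in the heart after loss of this gene. Totals of estimated counts were 17509564, 20969139, 22002638 and 24580953 in cKO replicates 1 to 4, 24008853 and 22145156 in floxed, and 25833259 and 21713560 in Cre. They did not differ beyond the spread of libraries between cKO and controls (exact two-sided permutation test over 70 splits, p = 0.257). The p values measure the spread between these hearts, each from 1 mouse as the labels describe them. Mitochondrial transcripts made up 24.1 ± 3.48% of counts in cKO and 27.5 ± 1.63% in controls (exact two-sided permutation test, p = 0.143). The first principal component held 57.1% of the variance and separated cKO (-67.1 to -18.1) from control libraries (36.4 to 49.1).

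Elmsan1 transcript (ENSMUSG00000042507, GRCm38 chromosome 12, 84149176 to 84218881, minus strand) was lower in every cKO heart than in every control heart. The 4 cKO libraries held 15.2, 15.5, 15.3 and 12 CPM, the floxed libraries 27.6 and 25.6 CPM, and the Cre libraries 28.6 and 25.3 CPM. The raw counts were 289, 314, 358 and 315 in cKO, 645 and 521 in floxed, and 754 and 504 in Cre. The fall was 1.85-fold (log2 fold change -0.89, SE 0.11; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 8.94e-05). The value counts the whole gene in whole heart, which holds other cell types, and the floxed exons are not given in the sources used here. Genes of the preset sex-linked list matched the male label in all 8 libraries, with 675 or more raw counts of Eif2s3y and at most 14.1 of Xist.

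**Figure D1:**
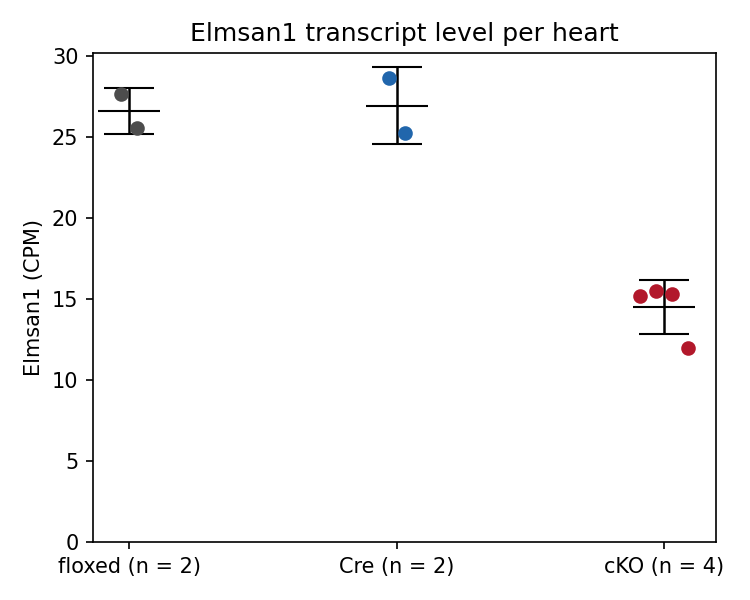
Elmsan1 level in CPM (y axis) for each heart (points) by group (x axis), with horizontal bars for the group mean and SD. The cKO hearts lie between 12 and 15.5 CPM, below all control hearts, which lie between 25.3 and 28.6 CPM.

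Lists of calcium handling, ion channel, desmosome and cardiomyocyte identity genes were lower in cKO than in the 2 control groups, while lists of endothelial, fibroblast and macrophage markers were higher in the same contrast. Among 20 calcium handling genes 13 fell and 4 rose. Atp2a2, the pump that returns calcium to the sarcoplasmic reticulum, fell from 13100 ± 439 to 5178 ± 959 CPM (SD, n = 4 each; log2 -1.34, SE 0.14). Ryr2, the calcium release channel, fell 2.53-fold (log2 -1.34, SE 0.11), and its partner Trdn 2.40-fold. Pln, the inhibitor of that pump, fell 2.09-fold, and Slc8a1, the sodium-calcium exchanger, 9.70-fold (log2 -3.28, SE 0.24), from 116 ± 17.9 to 11.97 ± 4.32 CPM. Of 25 ion channel and conduction genes 13 fell and none rose. Hcn4, the pacemaker channel, fell 5.51-fold, and the potassium channel genes Kcnj11 4.27-fold, Kcnd2 3.05-fold and Kcnj2 2.53-fold. Of 12 desmosome and intercalated disc genes 11 fell (12 when adjusted over the list alone), with Dsp, the desmosomal plaque protein, 3.75-fold lower, Ctnna3 4.05-fold, Cdh2 3.10-fold and Vcl 2.78-fold. Of 18 cardiomyocyte identity genes 10 fell and 3 rose (4 rose when adjusted over the list alone), among the falls Esrrg 4.14-fold, Tbx20 2.41-fold, Fgf13 2.33-fold and Gata4 2.11-fold. The camera adjusted p was 0.000205 for calcium handling, 8.41e-05 for ion channels, 1.29e-08 for the desmosome list and 0.0178 for the identity list. With an estimated correlation the adjusted p values were 0.324, 0.460, 0.420 and 0.562, so that none of these lists stayed called. All 4 lists were lower under every scaling tried.

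Lists of the tricarboxylic acid cycle, fatty acid oxidation, branched-chain amino acid and ketone use, and mitochondrial dynamics were lower as well. Of 16 tricarboxylic acid cycle genes 13 fell and none rose, with a median log2 fold change of -0.78. Among them, Ogdh fell 2.22-fold, Dld 2.18-fold, Suclg2 2.23-fold and Cs, citrate synthase, from 1220 ± 48.8 to 607 ± 87.6 CPM (SD, n = 4 each; log2 -1.01, SE 0.12). Of 26 fatty acid oxidation genes 18 fell, including Acadm 2.69-fold, Etfdh 2.56-fold and Acsl1 2.45-fold, and 1 rose, Etfb. Of 15 genes of branched-chain amino acid and ketone use 11 fell and none rose, with Aldh6a1 2.95-fold lower, Dbt 2.63-fold, Ppm1k 2.61-fold and Ivd 2.30-fold. Of 22 genes of mitochondrial dynamics and biogenesis 13 fell and 4 rose, among the falls Opa1 and Mfn2, which fuse mitochondria, at 2.71-fold and 2.21-fold, Tfb2m 2.10-fold and Gabpa 1.58-fold. Ppargc1a, a coactivator of mitochondrial genes, fell 2.57-fold (log2 -1.36, SE 0.11), and Ppara, the fatty acid receptor, 6.80-fold (log2 -2.77, SE 0.24). The PPAR target list as a whole split, with 5 up and 5 down of 21 and a camera adjusted p of 0.521, and its median (0.12) and its mean (-0.03) differed in sign. Camera adjusted p values were 2.76e-06 (tricarboxylic acid cycle), 0.000231 (fatty acid oxidation), 1.38e-08 (branched-chain and ketone use) and 0.00972 (mitochondrial dynamics). With an estimated correlation the adjusted p values were 0.587, 0.666, 0.460 and 0.562. Glycolysis genes included 7 up and 7 down of 24 (camera adjusted p = 0.332), with Hk2 2.67-fold and Pdha1 2.50-fold lower, Hk1 1.73-fold lower and Pgam2 1.96-fold higher. The median of that list was -0.10. It turned positive under library size alone (0.03) and under upper-quartile scaling (0.02), the latter chosen for lists after seeing the data. With an offset for transcript length and GC content, chosen after seeing the data, 3 rose and 12 fell, and the list was called lower (median -0.21, camera adjusted p = 0.0154). Without the offset its adjusted p with an estimated correlation was 0.758.

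Ribosomal protein genes and most genes of oxidative phosphorylation were higher in cKO, and both lists hold short transcripts. All 33 cytoplasmic ribosomal protein genes rose, with a median log2 fold change of 0.90, for example Rpl38 2.90-fold, Rps15 2.36-fold, Rpl32 2.32-fold and Rpl27 1.95-fold. Of 42 oxidative phosphorylation genes 25 rose and 7 fell. Ndufa2 and Ndufs6 of complex I rose 2.48-fold and 2.22-fold, while Ndufs1 of the same complex and Sdha of complex II fell 2.48-fold and 2.44-fold. Camera adjusted p was 4.38e-21 for ribosomal proteins and 0.000286 for oxidative phosphorylation, and with an estimated correlation the adjusted p was 0.562 and 0.666. The median longest transcript was 1059 bp in the first list and 1386 bp in the second, against 4438 bp for calcium handling and 2608 bp for the tricarboxylic acid cycle.

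Fold changes followed transcript length across the genome. The median log2 fold change fell from 0.79 in the shortest of 5 length classes (530 coding genes) to -0.40 in the longest (824 genes). Across 13744 coding genes, which are not independent replicates, Spearman's rho of log2 fold change was -0.396 with transcript length and 0.336 with GC content. In Cre against floxed the same values were 0.04 and -0.161. Per library, levels were taken as deviations from the mean of all 8 libraries. Their rho with length was -0.223 to -0.403 in the 4 cKO libraries and 0.312 to 0.351 in the 4 controls. Opposite signs in cKO and controls follow from this centring, so the values do not show which of them carries the trend. With an offset for length and GC, an alternative chosen after seeing the data, the oxidative phosphorylation median moved to -0.05 and its call ended (camera adjusted p = 0.943, range over the alternatives 3.55e-05 to 0.943). The ribosomal protein median moved to 0.44 and stayed called (camera adjusted p = 2.86e-08), but Rps15 (log2 0.18, edgeR adjusted p = 0.0662) and Rpl27 (log2 0.14, edgeR adjusted p = 0.121) did not. With the same offset Etfb (-0.02) and Pgam2 (0.13) were no longer called either. Falls of Atp2a2 (-0.996), Ryr2 (-0.93), Dsp (-1.56), Cs (-0.88) and Acadm (-1.39) remained called with the offset. The lists called lower stayed called by camera, most with smaller falls. Medians moved from -0.52 to -0.40 for calcium handling (11 down, 6 up), from -0.70 to -0.59 for desmosome genes (8 down) and from -0.51 to -0.32 for mitochondrial dynamics (15 down, 1 up). Those of ion channels (13 down, 2 up), fatty acid oxidation and immediate early genes moved the other way, to -0.658, -0.558 and -1.67.

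**Figure D2:**
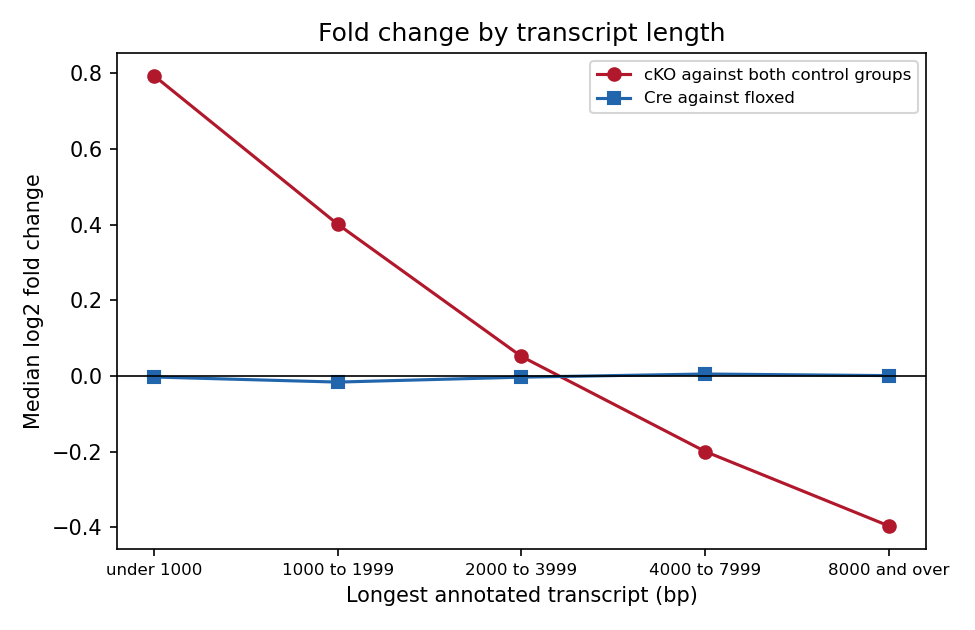
Median log2 fold change of coding genes (y axis) by length of the longest annotated transcript in bp (x axis), for cKO against both control groups (circles) and Cre against floxed (squares). The first falls from 0.79 for the shortest to -0.40 for the longest class, and the second stays near 0.

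Interferon response genes and markers of several non-muscle cell types were higher in cKO. Of 24 interferon response genes 22 rose and 1 fell, with Psmb8 2.48-fold, Xaf1 2.16-fold, Gbp3 2.05-fold and Oasl2 1.91-fold higher. Of 15 endothelial markers 11 rose and 1 fell, for example Ly6c1 2.74-fold, Egfl7 2.64-fold, Eng 1.76-fold and Tie1 1.72-fold. Of 16 fibroblast markers 7 rose and none fell, among them Pi16 2.21-fold, Meox1 2.18-fold, Dpt 1.57-fold and Dpep1 1.43-fold. Of 17 macrophage and monocyte markers 8 rose and none fell, including the complement genes C1qa 2.38-fold and C1qb 2.03-fold and the receptor gene Csf1r 1.41-fold. Of 16 atrial markers 10 rose and none fell, with Myl4 3.04-fold, Nppa 2.75-fold, Stard10 2.61-fold and Nr2f2 1.67-fold higher. Smooth muscle and pericyte markers were divided, 1 up and 2 down of 13 (camera adjusted p = 0.777), with Abcc9, also a cardiomyocyte channel subunit, 3.11-fold lower. Camera adjusted p was 6.70e-08 (interferon), 0.00118 (endothelial), 0.0131 (fibroblast), 0.00879 (macrophage) and 0.00800 (atrial). With an estimated correlation the adjusted p values were 0.587, 0.587, 0.666, 0.666 and 0.666. The fibroblast call was lost without Cre replicate 2 (median 0.21, camera adjusted p = 0.0510), and the atrial call without the genes it shares with other lists (camera adjusted p = 0.0766) and with the replicate block (0.0587). Under that block Nppa, Stard10 and Myl4 also lost their calls (edgeR adjusted p = 0.0882, 0.1 and 0.175). The block gives no weight to cKO replicates 3 and 4, whose numbers no control shares, so these losses can reflect fewer hearts.

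Stress markers of the heart did not move as a block. Of 25 fetal and hypertrophic genes 6 rose and 10 fell (11 when adjusted over the list alone; camera adjusted p = 0.197), and the median (-0.17) and mean (0.02) differed in sign. Nppa, the atrial natriuretic peptide gene, rose from 1616 ± 317 to 4430 ± 1378 CPM (SD, n = 4 each; log2 1.46, SE 0.24; 0.68 with the length and GC offset), whereas Ankrd1 fell 1.63-fold and Mef2a 1.76-fold, and Rcan1 fell 1.65-fold. Ccn1 fell 4.07-fold, a value carried by the floxed hearts (10.2-fold against floxed and 1.62-fold against Cre). Acta1, skeletal actin, rose 4.50-fold (log2 2.17, SE 0.65; edgeR adjusted p = 0.0350) and was not called when any 1 of 6 libraries was left out. Its edgeR adjusted p was then 0.0708, 0.0602 and 0.0571 without cKO replicate 1, 2 or 3, 0.0981 and 0.105 without floxed replicate 1 or 2, and 0.0745 without Cre replicate 1. Nppb (log2 0.56, SE 0.35) was not called, and neither were the myosin heavy chain genes Myh6 (-0.21, SE 0.12) and Myh7 (0.04, SE 0.53). Nppb was called without cKO replicate 4 (log2 0.81, edgeR adjusted p = 0.00091). With the replicate block Nppb (log2 0.92, edgeR adjusted p = 0.000206) and Myh7 (log2 0.64, edgeR adjusted p = 0.00843) were called higher. The Myh7 value averages -0.84 against floxed and 0.92 against Cre, neither of them called (edgeR adjusted p = 0.329 and 0.324). Among 24 sarcomere genes 12 fell and 6 rose (7 when adjusted over the list alone; camera adjusted p = 0.246), with Nebl 2.44-fold and Myom2 2.07-fold lower and Tcap 2.39-fold and Tnnc1 1.61-fold higher. With the length and GC offset Tcap (0.35) and Tnnc1 (-0.06) were no longer called, and the sarcomere list was (camera adjusted p = 0.00521; 0.758 with an estimated correlation and no offset). Of 33 extracellular matrix genes 10 rose and 1 fell (camera adjusted p = 0.0748), including Timp1 4.05-fold, Tgfb1 1.82-fold, Cilp 1.82-fold and Postn 1.56-fold, while Col1a1 (0.39, SE 0.26) and Col3a1 (0.15, SE 0.35) were not called. That list passed the threshold without cKO replicate 2 (camera adjusted p = 0.0290), without cKO replicate 3 (0.0384) and without Cre replicate 1 (0.0294), and with the length and GC offset on all libraries (median 0.36, camera adjusted p = 0.0254). Its adjusted p with an estimated correlation and no offset was 0.758. Of 22 unfolded protein response and heat shock genes 11 fell and 1 rose (camera adjusted p = 0.0361), with Hspa5, the reticulum chaperone, 2.09-fold lower, Hyou1 1.91-fold, Hspd1 1.80-fold and Dnajb9 1.71-fold. With an estimated correlation that adjusted p was 0.666. Its camera call was also lost without cKO replicate 1 (adjusted p = 0.0620), without cKO replicate 3 (0.0647) and without Cre replicate 2 (0.0905), and with a filter at 1 CPM (0.0726) and pooled controls (0.0721).

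Partners of Elmsan1 changed unevenly. Hdac2 fell 1.52-fold (log2 -0.60, SE 0.08), while Hdac1 (0.10, SE 0.10) and Dnttip1 (0.10, SE 0.10) were not called. Of the 5 MiDAC genes tested 2 fell, Elmsan1 itself and Hdac2, and the list was not called (camera adjusted p = 0.357), with a positive median (0.10) and a negative mean (-0.21). With the length and GC offset its median turned to -0.23, still not called (camera adjusted p = 0.304). Dnttip1 was then at -0.23 (edgeR adjusted p = 0.0654), and Hdac2 stayed called at -0.39. In other class I deacetylase complexes 12 of 25 genes fell and 4 rose (camera adjusted p = 0.0690), with Ncor1 2.03-fold, Rcor1 1.68-fold, Tbl1x 1.58-fold and Rbbp7 1.54-fold lower. That list was called without floxed replicate 2 (camera adjusted p = 0.0430) and with no filter (0.00418). With an estimated correlation on all libraries its adjusted p was 0.587. Among 23 chromosomal neighbours of Elmsan1, 8 fell and 4 rose (camera adjusted p = 0.197), with Aldh6a1 2.95-fold, Ptgr2 1.82-fold and Entpd5 1.77-fold lower and Ltbp2 1.77-fold higher. The share of neighbours called was close to the 52.1% of all tested genes called in this contrast. Of the axon guidance genes, Ntn1 fell 1.81-fold (log2 -0.85, SE 0.13), and Slit3 was not called (log2 -0.38, SE 0.15; edgeR adjusted p = 0.0514) except without Cre replicate 2 (edgeR adjusted p = 0.00233), among other settings. Pdk4 (-0.78, SE 0.41) and Cdkn1a (0.30, SE 0.41) were not called. Pdk4 was called without cKO replicate 3 (log2 -1.24, edgeR adjusted p = 0.00287) and with the replicate block (log2 -1.34, edgeR adjusted p = 0.00824).

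The largest rise among named genes was that of Pcdhgc4, 1 of the alternative first-exon genes of the gamma protocadherin cluster, at 43.7 ± 9.94 CPM in cKO and 2.60 ± 1.72 CPM in controls (SD, n = 4 each; log2 4.17, SE 0.32). Its exons overlap the rest of the cluster. The total of the whole cluster, Pcdhgc4 included, was lower in cKO, 103.5 ± 6.86 against 131.6 ± 6.74 CPM (exact two-sided permutation test over 70 splits, p = 0.0286, the smallest it can give). Since Pcdhgc4 rose, the rest of the cluster fell by more than this total, and 13 other cluster genes were called lower. How reads were assigned among these overlapping genes was not tested. The permutation test of the cluster total only shows that its cKO and control values did not overlap. That held for 49.3% of all tested genes, and the cluster was not among the preset lists. Mt3, a metallothionein, rose 6.06-fold, Tnfrsf25 4.36-fold, Hamp, the iron hormone hepcidin, 4.28-fold, Tbx6 4.16-fold and Gamt, the enzyme that completes creatine synthesis, 4.13-fold, and none of these overlaps another gene. With the length and GC offset these rises stayed called at smaller log2 values, 1.56 for Mt3 (2.60 without), 1.63 for Tnfrsf25 (2.12), 1.49 for Hamp (2.10), 1.61 for Tbx6 (2.06) and 1.23 for Gamt (2.05). Sap25 (8.47-fold), Eif4ebp3 (6.84-fold), Insl3 (6.43-fold) and Col7a1 (4.24-fold) also rose, and their exons overlap other annotated genes. Eif4ebp3 lost its call without cKO replicate 4 (edgeR adjusted p = 0.0502), with DESeq2 (0.0858), with no filter (0.0909) and with the replicate block (0.109), under which Hamp lost it too (0.132). Insl3 lost its call without the 2 floxed libraries (0.0660), and Eif4ebp3 and Insl3 lost it with the length and GC offset (edgeR adjusted p = 0.0659 and 0.0729).

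The largest falls included Nt5c1a, which makes adenosine from AMP, at 0.354 ± 0.272 CPM in cKO and 11.8 ± 2.21 CPM in controls (SD, n = 4 each; log2 -5.03, SE 0.36), and Pm20d2, 14.7-fold lower, neither of which overlaps another gene. Fosb and Fos fell 16.1-fold and 14.7-fold in this contrast, and 3.91-fold and 4.69-fold against Cre alone. Zxda (35.8-fold, annotated as a pseudogene), Serinc4 (23.9-fold), Pdpr (11.5-fold), Pakap (11.02-fold) and Slc8a1 overlap other annotated genes, and Srp54a (11.7-fold) has near-identical copies, so reads could have been divided differently among them. Srp54a lost its call when 1 of 5 libraries was left out, and with library size alone (edgeR adjusted p = 0.0521), DESeq2 (0.113), no filter (0.0606) and the replicate block (0.146), under which Serinc4 lost it too (0.0519). The log2 fold change of Srp54a had an edgeR adjusted p of 0.0542 without cKO replicate 1, 0.0783 without floxed replicate 1, 0.0874 without floxed replicate 2, 0.0790 without Cre replicate 1 and 0.0776 without Cre replicate 2.

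In total, edgeR's quasi-likelihood test called 7959 of 15289 genes (52.1%) in this contrast, 3909 higher and 4050 lower. Of these, 2074 changed by at least 1 on the log2 scale, 1152 up and 922 down. The 4 cKO values lay on 1 side of the 4 control values for 7539 genes (49.3%, where chance gives 2.86%). Upper-quartile scaling and library size alone moved the median of all genes to 0.14 and 0.15, from 0.03 with TMM, and raised the share of higher calls from 49.1% to 59.3% and 61.5%, so directions of small changes are relative to TMM. The labels give no library or sequencing batch, so no comparison within a batch could be made.

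**Figure D3:**
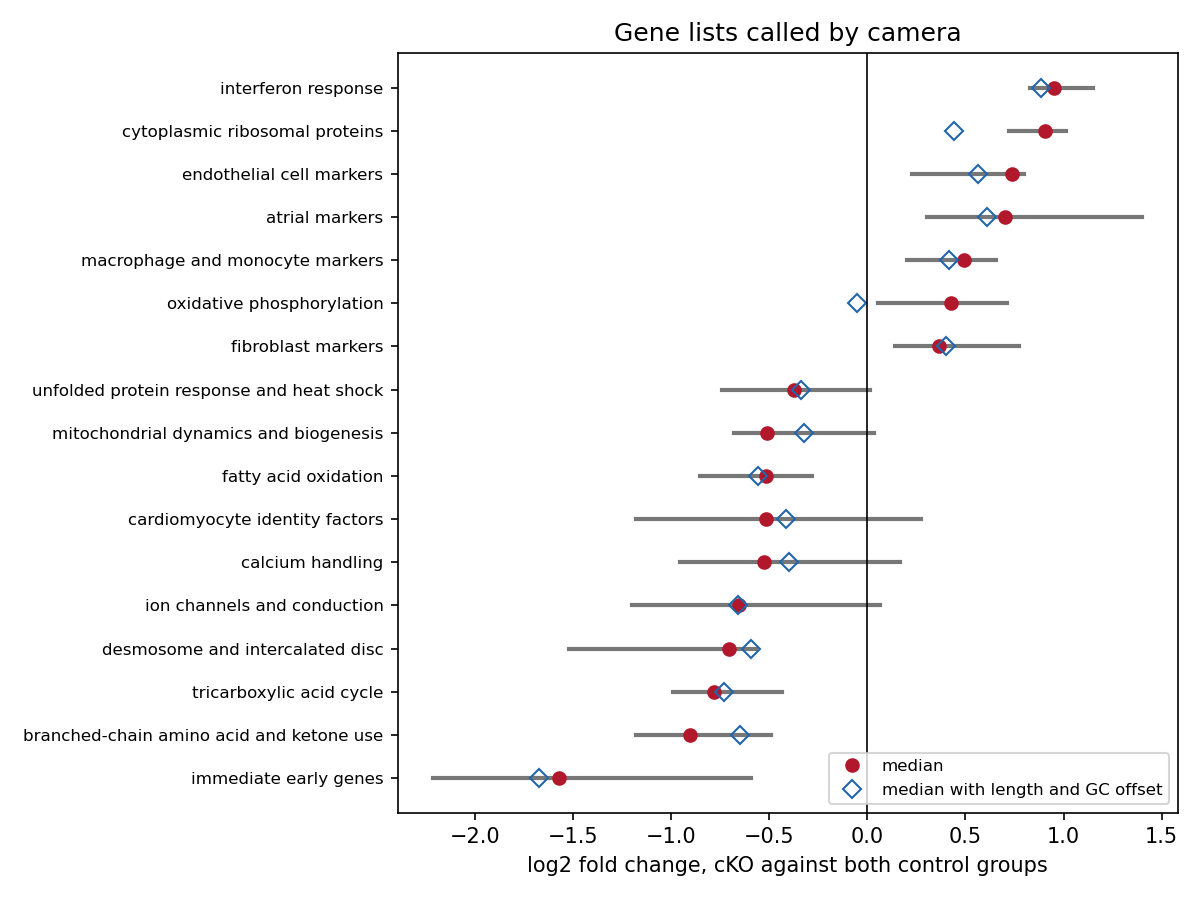
Median log2 fold change (x axis) of the 17 gene lists called by camera (y axis) for cKO against both control groups, as circles, with grey lines from the first to the third quartile of members. Diamonds show the median with the length and GC offset, which moves oxidative phosphorylation from 0.42 to -0.05 and leaves the tricarboxylic acid cycle at -0.73.

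Immediate early genes, which respond within minutes to stimulation, were highest in the 2 floxed hearts. Fos was at 263 and 287 CPM in floxed, 41.0 and 15.0 CPM in Cre, and 4.32 to 8.49 CPM in cKO. Of 23 such genes 15 fell in cKO against both control groups (17 when adjusted over the list alone), including Btg2 5.09-fold, Jun 3.27-fold and Egr2 6.62-fold (1.91-fold, 1.69-fold and 2.07-fold against Cre alone), with a median of -1.57 (camera adjusted p = 4.92e-09). The adjusted p was 0.324 with an estimated correlation. The camera call ended without the 2 floxed libraries (median -0.56, adjusted p = 0.0919), a fit chosen after seeing the data, and with pooled controls (adjusted p = 0.0609), where the median was not smaller (-1.81). Without those libraries Egr2 was not called (log2 -1.03, edgeR adjusted p = 0.0557).

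**Figure D4:**
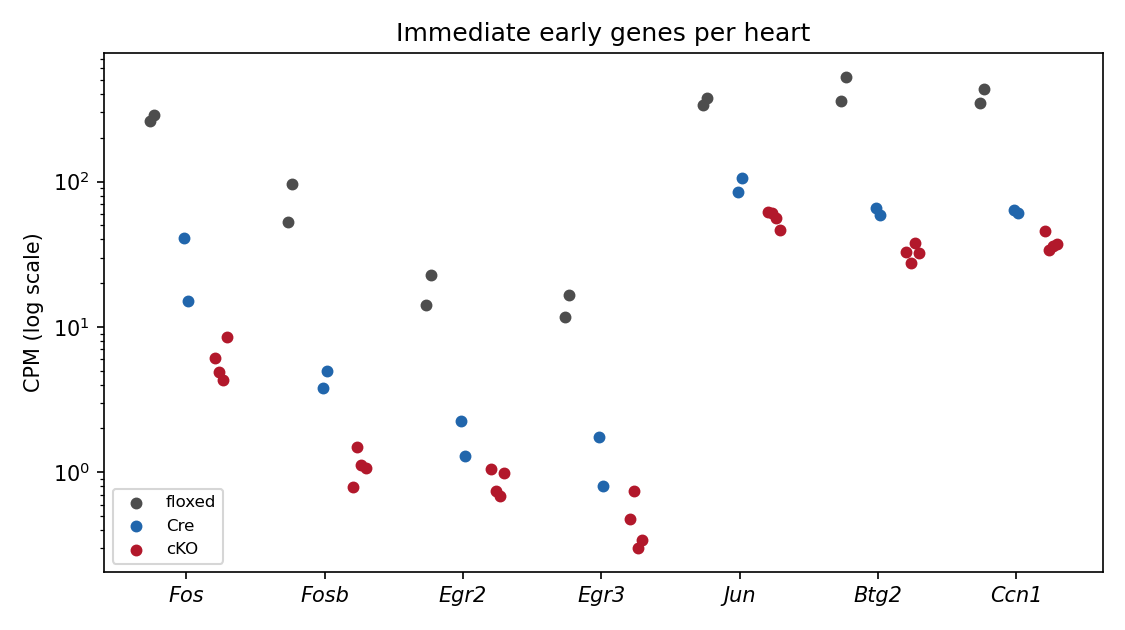
Levels in CPM on a log scale (y axis) of 7 genes induced early after stimulation (x axis) in each heart, coloured by group. Both floxed hearts lie above all Cre and cKO hearts for each gene, with Fosb at 52.9 and 95.5 CPM in floxed and 0.789 to 1.48 CPM in cKO.

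Compared with floxed hearts alone, cKO hearts had lower immediate early, tricarboxylic acid cycle and calcium handling genes. Elmsan1 was 26.6 ± 1.44 CPM in floxed (SD, n = 2) and 14.5 ± 1.68 CPM in cKO (SD, n = 4; log2 -0.88, SE 0.13). Of 23 immediate early genes 19 fell, with a median of -2.48 (camera adjusted p = 7.44e-26; adjusted p = 0.0933 with an estimated correlation). Fosb fell by 6.05 and Fos by 5.52 on the log2 scale (SE 0.27 and 0.41). Of the tricarboxylic acid cycle genes 14 of 16 fell (median -0.80), and of calcium handling genes 14 of 20 (median -0.57). Their camera adjusted p was 1.26e-06 and 6.42e-05, and with an estimated correlation the adjusted p was 0.613 and 0.209. Beside Pcdhgc4 (4.76, SE 0.45) and Sap25 (3.56, SE 0.80), the largest named rises were in Apoc1 (4.59, SE 1.52), an apolipoprotein gene, and Adig (3.04, SE 0.90), an adipocyte gene. Apoc1 lay at 8.86 and 7.54 CPM in cKO replicates 3 and 4 and at 0.842 and 0.741 CPM in the other cKO hearts. Against both control groups the edgeR adjusted p of Apoc1 was 0.0792 without cKO replicate 4, 0.120 and 0.102 without floxed replicate 1 or 2, and 0.105 and 0.0946 without Cre replicate 1 or 2, and that of Adig 0.0768 without floxed replicate 1 and 0.0596 and 0.0543 without Cre replicate 1 or 2. Both also lost that call with limma voom (0.214 and 0.0983), with no filter (0.0884 and 0.0817), with the replicate block (0.0848 and 0.144) and with the length and GC offset (0.0770 and 0.0785). Zxda fell by 5.53 (SE 0.75), and Rpl35a-ps4, a ribosomal pseudogene, was at 6.98 and 3.98 CPM in floxed and 0 in all other libraries, so no fold is given. edgeR's quasi-likelihood test called 6559 genes (42.9%), 3031 higher and 3528 lower. The count was 3600 without floxed replicate 1 and 3624 without floxed replicate 2, where the lone floxed library is assumed to vary like the other groups, and the share of higher calls went from 46.2% to 58.8% with upper-quartile scaling and 61.1% with library size alone.

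Compared with Cre hearts, which carry the same transgene, cKO hearts had lower tricarboxylic acid cycle, calcium handling and desmosome genes and higher interferon response genes. Elmsan1 was 26.9 ± 2.39 CPM in Cre (SD, n = 2) and 14.5 ± 1.68 CPM in cKO (SD, n = 4; log2 -0.90, SE 0.13). Of the tricarboxylic acid cycle genes 12 of 16 fell (median -0.77), of calcium handling genes 12 of 20 (median -0.48) and of desmosome genes 11 of 12 (median -0.75). Their camera adjusted p was 1.09e-05, 0.000311 and 2.06e-08, and with an estimated correlation the adjusted p was 0.661, 0.587 and 0.629. Interferon response genes rose in 20 of 24 cases (median 1.04, camera adjusted p = 3.75e-08; adjusted p = 0.661 with an estimated correlation). Among 23 immediate early genes 7 fell and 2 rose (median -0.56, camera adjusted p = 0.141; adjusted p = 0.661 with an estimated correlation). The falls include Fos 4.69-fold (SE 0.40 on the log2 scale), Fosb 3.91-fold (SE 0.30), Egr3 2.84-fold, Egr2 2.07-fold, Btg2 1.91-fold and Jun 1.69-fold. The rises were Ier2 and Jund, 2 names outside the naming rule and chosen after their values were seen. Under the length and GC offset 8 fell and none rose, and camera called the list lower (median -0.73, adjusted p = 0.00274). The largest named rises were Pcdhgc4 (3.58, SE 0.40), Gsta1 (2.80, SE 0.81), a glutathione transferase gene, Mt3 (2.65, SE 0.33) and Sap25 (2.61, SE 0.72). Gsta1 lost its call against both control groups without Cre replicate 1 (edgeR adjusted p = 0.0511), with limma voom (0.131), with no filter (0.0527) and without the 2 Cre libraries (0.0888). The largest falls were Nt5c1a (-4.83, SE 0.39), Zxda (-4.80, SE 0.77), Serinc4 (-4.48, SE 0.56) and Srp54a (-3.65, SE 1.14). edgeR's quasi-likelihood test called 6484 genes (42.4%), 2997 higher and 3487 lower. The count was 3929 without Cre replicate 2, and the share of higher calls went from 46.2% to 57.3% with library size alone.

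The 2 control groups differed mainly in immediate early genes, which were lower in Cre than in floxed hearts. Fosb was at 4.40 ± 0.858 CPM in Cre and 74.2 ± 30.1 CPM in floxed (SD, n = 2 each; log2 -4.08, SE 0.31), and Egr3 (-3.43, SE 0.39) and Egr2 (-3.36, SE 0.32) fell with it. Of the 23 genes of that list 9 fell (18 when adjusted over the list alone) and none rose, with a median of -1.92. The camera adjusted p was 7.33e-152, and the call held with an estimated correlation (adjusted p = 0.000905). Fos fell by 3.29 on the log2 scale without passing the test (SE 0.48; edgeR adjusted p = 0.156). Elmsan1 did not differ (log2 0.02). edgeR's quasi-likelihood test called 15 genes, 14 lower and 1 higher, where 526 passed an unadjusted p of 0.05. Besides immediate early genes, the 14 include Rpl35a-ps4, at 0 in both Cre libraries. The 1 higher gene, outside the naming rule and picked after its value was seen, has no symbol (ENSMUSG00000106852) and was at 1.37 and 2.00 CPM in Cre and 0 in floxed. Among other lists, camera called fetal and hypertrophic (adjusted p = 4.68e-05), inflammation (0.0282) and circadian clock genes (5.66e-07) lower and cell cycle (0.000869), erythroid (0.0270) and adipocyte genes (0.000136) higher in Cre. With an estimated correlation the adjusted p was 0.570 for the clock list, 0.862 for inflammation and 0.992 for the other 4, and at most 1 gene of each was called. The count was 7 without floxed replicate 2 and 9 without Cre replicate 1 or Cre replicate 2, and 57 with DESeq2.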

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

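The test of the immediate early genes and the length and GC offset were chosen after the data had been seen. Of 193 groups of 4 cKO values examined, 10 had a library far from the other 3, and chance alone gives about 1 in 20. In cKO replicate 4 Elmsan1 was 12 CPM against 15.2 to 15.5 CPM in the others, Myh6 was 16700 CPM against 21700 to 22100 CPM, and Fbxo32 was 55.4 CPM against 80.6 to 82.6 CPM. In the same library Col1a1 was 257 CPM against 126 to 148 CPM, Col3a1 484 CPM against 189 to 235 CPM, and Mcm6 12 CPM against 9.76 to 10.1 CPM. Tcap was 3410 CPM in cKO replicate 2 against 2550 to 2640 CPM, Notch3 was 56.4 CPM in cKO replicate 1 against 40.9 to 43.3 CPM, and Zxda was 0.214 CPM in cKO replicate 3 and 0 in the others. Mitochondrial transcripts were 29.3% of counts in cKO replicate 2 against 22.1% to 22.6% in the others. The effect of cKO against floxed differed from that against Cre for 7 named genes, as tested by Cre against floxed. The log2 difference was -4.08 for Fosb, -3.43 for Egr3, -3.36 for Egr2, -2.65 for Ccn1, -2.83 for Btg2 and -1.91 for Jun. The fitted difference of -9.94 for Rpl35a-ps4 depends on the prior count, since its Cre libraries are at 0, and is no bound.

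A share of 52.1% of tested genes changed in cKO, and other splits of the hearts argue against a random grouping as its source. Over 100 of 210 splits of the 8 libraries, 3 gave at least the 7959 genes of the real one, with 8308 in the highest other. The 2 others also part all cKO from all controls, with the 4 controls as the group of 4, and the 95 splits that mix cKO with controls gave at most 2 genes. Mixing puts the difference between cKO and controls inside the groups and raises their spread, so low counts there follow from that difference. The splits cannot address a factor that follows the groups. A trend with transcript length and GC content, as the offset models it, is argued against as the whole cause, since 7020 genes passed with the offset. Of the 7959 calls without it, 5461 stayed in the same direction and 56 turned, and the rest did not stay called. The 7020 therefore also hold genes that were called only with the offset. The offset uses the longest annotated transcript, so a length bias that it does not capture could remain. Loss of Elmsan1 stays open as a hypothesis beside a difference in RNA quality or library batch that follows the groups, which the labels do not give and which cannot be told apart from genotype.

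Immediate early genes separated the floxed hearts from both groups with Cre. Both control groups held Elmsan1 at 26.6 and 26.9 CPM, so its loss does not enter the difference between them (median -1.92). For cKO against Cre the median was -0.559, between the bounds set for and against an effect of the deletion. Of 23 genes 7 were lower there and 2 higher, with log2 -2.23 (SE 0.40) for Fos and -1.97 (SE 0.30) for Fosb, and camera called the list lower with the length and GC offset (adjusted p = 0.00274) but not without it (0.141, and 0.661 with an estimated correlation). For this smaller difference the loss of Elmsan1 cannot be told apart from the way or time of collecting the hearts, which with the Cre transgene are untested candidate explanations between the control groups.

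Some gene models with the largest changes overlap other genes, so reads that are shared between neighbours may have moved between them. Of the 249 annotated models called with an absolute log2 fold change of at least 2, 41.8% overlap exons of another gene (95% exact binomial interval 35.6% to 48.2%), against 38.1% of the 15216 annotated models tested (Fisher's exact test, p = 0.237). The bound set beforehand against this explanation was a share of at most 41.9%, which the 41.8% met by a small margin. The interval reaches above that bound, so the overlap stays open for the models that have one. The other 145 models overlap no exon of another gene, Nt5c1a, Pm20d2 and Mt3 among them.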

How the results depend on the processing

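The length and GC offset, the fits without both floxed or both Cre libraries, and upper-quartile scaling for the gene lists were chosen after seeing the data. Elmsan1 stayed lower and called in the 21 alternative fits, from -0.952 to -0.712, but at -0.886 it lies short of the minimum absolute log2 change of 1. For cKO against both control groups the count was 6536 to 8209 with 1 library left out, 5812 without the 2 floxed and 6342 without the 2 Cre libraries, and 7692 with DESeq2. A minimum absolute log2 change of 1 left 2074 genes there, 1956 against floxed and 1824 against Cre, by its own construction. With 1 library left out the counts were 3600 to 7037 against floxed, 3929 to 6934 against Cre and 7 to 18 for Cre against floxed. The last count, 15, became 57 with DESeq2, 31 without a filter and 32 in a fit of those 2 groups alone, and the cause was not tested. The fit of all 8 libraries shares 1 estimate of spread with the cKO hearts, most of whose pairs differed more. Chi-square per degree of freedom was 14.5 to 52.5 between cKO libraries, 13.9 between floxed and 16 between Cre libraries. Of 44 lists 17 were called, 0 by camera with an estimated correlation, which allows for the correlation among members, and 26 by fry, which does not compare a list with other genes. Replicate numbers were shared between groups, but correlations of same-numbered libraries were -0.07 to 0.07, so they do not pair the hearts. With the replicate block the counts were 6372 for the main contrast, 5332 against floxed, 5285 against Cre and 84 for Cre against floxed, and the epicardial list turned from 0.15 to -1.37. The block gives no weight to cKO replicates 3 and 4, whose numbers no control shares. Changes under it in the cKO contrasts can therefore reflect fewer hearts. With the length and GC offset, which removes a trend that favours short transcripts, 5 of 191 named genes turned sign with a call before or after, Tnnc1 (-0.0648), Etfb (-0.0236), Map1lc3a (-0.236), Hist1h4i (-0.0692) and Kdm5d (0.104), 4 of these 5 and 24 others lost their call, and 1 gained it. In the simulations 1.5-fold changes were recovered for 50.5% of genes in the main contrast and 14.1% to 22.3% in the others, and depth alone was not varied. Far fewer genes were changed there than were called in the cKO contrasts, which makes the adjusted threshold stricter. The shares therefore do not measure what the cKO contrasts missed. For Cre against floxed, where few genes were called, small changes were probably often missed (14.6% recovered).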

Other observations

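Of 13 genes encoded by mitochondrial DNA 6 fell and 1 rose in cKO (camera adjusted p = 0.236), with mt-Nd5 2.20-fold, mt-Atp8 2.70-fold and mt-Nd4l 2.63-fold lower and mt-Nd3 1.84-fold higher, and mt-Nd5, mt-Atp8 and mt-Nd4l overlap their neighbours. The rise of mt-Nd3 lost its call without the 2 Cre libraries (log2 0.74, edgeR adjusted p = 0.0544). The list was called lower without cKO replicate 2 (camera adjusted p = 0.00664). With the length and GC offset, chosen after seeing the data, it was called lower as well, with 10 down and 1 up (median -0.56, camera adjusted p = 4.02e-05). Without the offset its adjusted p with an estimated correlation was 0.758. Of 22 antioxidant genes 9 rose (12 when adjusted over the list alone) and 6 fell (camera adjusted p = 0.174), with Gpx4 2.20-fold, Gpx1 2.15-fold and Sod1 1.94-fold higher and Txnip 2.33-fold lower. In the integrated stress response list 7 of 21 rose and 3 fell (camera adjusted p = 0.438), with Ddit3 2.15-fold and Atf5 1.56-fold higher and Slc7a1 2.41-fold and Aldh1l2 2.07-fold lower. Of 18 circadian clock genes 4 rose and 5 fell (camera adjusted p = 0.639), with Clock 2.09-fold and Bhlhe40 1.75-fold lower and Dbp 1.94-fold and Tef 1.59-fold higher. Among 17 glucocorticoid and fasting genes 5 rose and 4 fell (camera adjusted p = 0.973), with Fbxo32 2.31-fold and Trim63 1.86-fold, ubiquitin ligases of muscle atrophy, lower and Mt1 3.12-fold higher. In the clock and glucocorticoid lists the share of members called was close to the 52.1% of all tested genes. With the length and GC offset Gpx4, Atf5 and Dbp were no longer called (log2 0.30, 0.15 and 0.47).

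Of 23 p53 and DNA damage genes 4 rose and 7 fell (camera adjusted p = 0.622), with Btg2 5.09-fold (1.91-fold against Cre alone) and Ccng1 2.27-fold lower and Bax 2.29-fold higher. Autophagy and lysosome genes fell in 7 and rose in 3 of 22 cases (camera adjusted p = 0.246), with Lamp2 1.67-fold and Atg5 1.62-fold lower. In the axon guidance list 8 of 26 fell and 2 rose (camera adjusted p = 0.272), with Neo1 2.08-fold and Plxna1 1.99-fold lower. The medians of these 3 lists (-0.01, -0.09 and -0.03) turned positive under upper-quartile scaling (0.11, 0.02 and 0.08), chosen for lists after seeing the data. Cell cycle genes had 7 up and 4 down of 31 (6 up when adjusted over the list alone; camera adjusted p = 0.269), and Ccnd3 was 1.43-fold higher and Cenpf 2.52-fold lower. Inflammation genes had 4 up and 3 down of 22 (2 and 0 when adjusted over the list alone; camera adjusted p = 0.639), with Casp1 1.91-fold higher. Casp1 lost its call without the 2 floxed libraries (log2 0.58, edgeR adjusted p = 0.129). Of 13 tested genes normally silent in adult ventricle 4 rose (3 when adjusted over the list alone; camera adjusted p = 0.105), with Stmn2 1.73-fold and Tnnt3 4.49-fold higher, and the list was called without Cre replicate 1 (camera adjusted p = 0.0376). Its adjusted p was 0.735 with an estimated correlation on all libraries.

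Markers of rarer cell types were not called as lists in the main contrast. Schwann and neuronal markers had 6 up of 11 (camera adjusted p = 0.141; 0.0354 without Cre replicate 1), lymphocyte and neutrophil markers 2 up of 13 (1 when adjusted over the list alone; 0.357) and adipocyte markers 2 up of 12 (1 when adjusted over the list alone; 0.177; 0.0301 without cKO replicate 2). On all libraries an estimated correlation gave an adjusted p of 0.666 for the Schwann and 0.758 for the adipocyte list, and 3 Schwann markers were called higher with the length and GC offset. Fabp4, which the endothelial list also holds, rose 2.61-fold, and Csf3r, a neutrophil receptor gene, 2.41-fold. Erythroid markers had 1 up of 9 (camera adjusted p = 0.286), and epicardial markers 1 up of 11 (0 when adjusted over the list alone; 0.777). Of 6 histone genes 3 rose and 1 fell (2 fell when adjusted over the list alone; camera adjusted p = 0.332), with Hist1h4h 2.27-fold higher, and of 4 tested sex-linked genes 3 fell (0.367), Uty 1.40-fold. None of these 3 was called with the length and GC offset (log2 -0.12 for Uty).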
